A study of Mus musculus with 16 samples.

How the data were processed

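The series holds polyA-selected, strand-specific RNA-seq of mouse hearts from 16 libraries, 4 each of WT and R502W at 3 weeks and at 18 weeks. The hearts were kept in RNAlater and RNA was extracted with TRI reagent and a column, per the labels' protocols. The labels give no batch, litter, sex or zygosity. The deposited signal values are linear CPM scaled by the authors' normalization factors. Per the submitters' processing notes, cutadapt, FastQC, RSEM and limma were used with the mouse build GRCm38, and the tool versions are not given in the sources used here. Each value equals a read count plus 0.5, divided by an effective library size, in CPM. Solving for the read counts gave whole numbers for 100% of values in every library, with a tolerance of 0.01 reads, although RSEM, which estimates fractional counts, is named. The effective sizes equal those of edgeR's trimmed mean of M-values, recomputed from the recovered reads, with scaling factors from 0.908 to 1.12. The smallest deposited value of a library therefore stands for 0 reads, and between 26 and 53 of the 14109 genes had 0 reads in a library.

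Gene identifiers were matched to the GENCODE annotation of GRCm38: 14103 matched, 13951 with the same symbol, 12824 of them protein coding and 322 pseudogenes. A symbol stood on at least 2 identifiers in 10 cases. Recovered reads per library ranged from 17521147 to 30672577. No gene was filtered out. Because reads were assigned by the authors' counting, values of multigene families (globins, class II histocompatibility genes, ribosomal proteins) and of mitochondrial genes with nuclear copies may be split between copies and are uncertain. Reads resembling nuclear copies of mitochondrial genes took 6.37% to 8.62% of each library. No pair of libraries of the same group was a duplicate, with a chi-square per degree of freedom of at least 7.36. Pairs from different groups were not compared.

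Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, with a group-means model over all 16 libraries so that the groups share the estimate of the spread, and empirical Bayes moderation with a mean-variance trend. The contrasts were R502W minus WT at each age, 18 minus 3 weeks in each genotype, and the interaction of genotype and age. Tests were two-sided and p-values were adjusted by Benjamini and Hochberg over all genes of a contrast, with a threshold of 0.05 and no fold minimum. Gene lists were tested with camera, which compares a list with the other genes, at its preset correlation of 0.01, with adjustment over the 46 lists with at least 5 measured genes out of 52 fixed lists. Beside it were run camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, 1 way. The test, the contrasts, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except those said to be chosen after.

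Named genes are Mybpc3, a fixed panel of 15 cardiac and matrix genes given whatever their result, and the 8 largest rises and 8 largest falls of each contrast. The latter are taken among called genes with a mean level above the median, no overlap between the libraries of the groups, and an established name. Up to 4 members with the smallest adjusted p are named for each list described, and any other gene is said to be chosen after its values were seen. Some genes that this rule names are not reported here. Of the called genes, 655, 1009, 2640 and 3194 were above the median level at 3 weeks, at 18 weeks, with age in WT and with age in R502W, and the groups did not overlap for 613, 820, 2159 and 2761 of these.

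Alternatives were other pseudocounts, filters on low values, quantile normalization, median-of-ratios rescaling, a fit of only the groups compared, other spread models, library weights, the sample number as a block, leaving out each library, and tests of the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. The edgeR test called 897 genes at 3 weeks, 1463 at 18 weeks, 4166 with age in WT and 5013 with age in R502W. A covariate for atrial markers, a fit without 2 libraries apart in these markers, a correction for GC content and thinning of all libraries to 17521147 reads were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

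The procedure was tested on simulated data drawn for the 14109 genes with the library sizes and the spread per gene of these samples. Each gene was drawn independently, so variation that genes share within a library was not simulated. At 3 weeks it recovered 69.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold. At 18 weeks the shares were 59.7%, 82.1% and 100%, for age in WT 56.7%, 77.6% and 98.5%, and for age in R502W 61.2%, 83.6% and 97.0%. For the interaction they were 38.8%, 59.7% and 83.3%. No changed gene was called in the wrong direction, and 3 to 6 unchanged genes were called per contrast. The shares hold for this simulation and need not be those of the real data.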

Results

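Hearts of R502W and wild-type (WT) mice were profiled at 3 and 18 weeks of age by strand-specific RNA-seq of polyA-selected RNA. R502W is a missense variant of cardiac myosin-binding protein C, the thick-filament protein encoded by Mybpc3. The study concerns hypertrophic cardiomyopathy and asked how this genotype and age alter cardiac gene expression. There were 4 groups of 4 libraries, 16 in all, and 14109 genes were measured. The recovered reads ranged from 17521147 to 30672577 per library. Transcripts encoded by the mitochondrial genome took 20.5% to 26.1% of the reads, and the 10 largest genes took 25.7% to 32.4%. The first principal component held 38.0% of the variance and separated the ages. The second held 15.1% and separated the genotypes. The labels do not say whether the libraries of a group came from separate litters or animals, so p-values measure only the spread between these samples. Levels are CPM, read counts scaled to library size, and fold changes are on the scale of log2(value + 1), which understates the change of genes with low values.

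Mybpc3 (chromosome 2, from 91118144, GRCm38), the gene that carries the variant, was transcribed in every library and was higher in R502W hearts at both ages. Its level was 2532 ± 64.4 (SD, n = 4) in WT and 3106 ± 193 (SD, n = 4) in R502W at 3 weeks, and 2986 ± 222 (SD, n = 4) and 3868 ± 263 (SD, n = 4) at 18 weeks. The single libraries lay between 2445 and 2587 in WT and between 2830 and 3263 in R502W at 3 weeks. They lay between 2735 and 3244 in WT and between 3544 and 4098 in R502W at 18 weeks, and the genotypes did not overlap at either age. The rise was 0.29 on the log2 scale at 3 weeks (SE 0.07, limma adjusted p = 0.0187) and 0.37 at 18 weeks (SE 0.07, limma adjusted p = 0.00217). Mybpc3 also rose with age, by 0.24 in WT (adjusted p = 0.0181) and by 0.32 in R502W (adjusted p = 0.00208). The genotype effect did not differ detectably between ages (difference 0.08, adjusted p = 0.812). The call at 3 weeks was lost without WT sample 1, WT sample 2 or R502W sample 3 of that age, where the adjusted p was at most 0.0569. Under quantile normalization the genotype effect at 3 weeks was 0.47, the age effect was 0.15 in WT (adjusted p = 0.167) and 0.07 in R502W (adjusted p = 0.525). In WT it also lost its call without WT 3 weeks sample 1, WT 18 weeks sample 1 or WT 18 weeks sample 4. The 22 measured genes beside Mybpc3 on chromosome 2 did not move as a list at 3 weeks (camera adjusted p = 0.472) or at 18 weeks (camera adjusted p = 0.688). The values carry gene counts only, so the variant itself was not read from them.

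**Figure D1:**
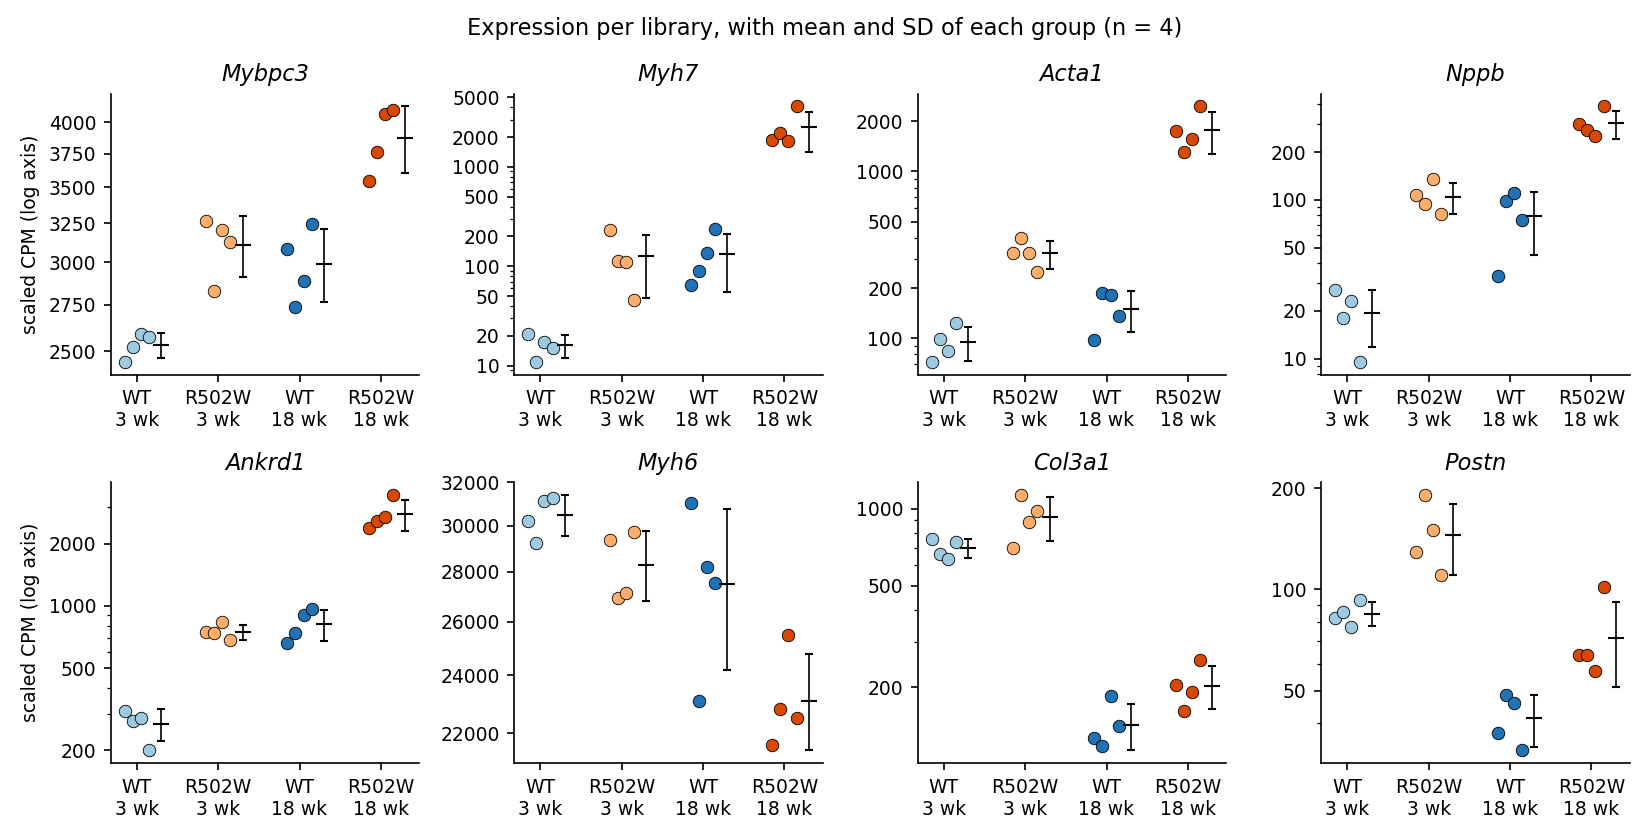
Scaled CPM (log axis) of 8 genes in each of the 16 libraries, by genotype and age, with the mean and SD of each group of 4 beside the points. Myh7 averaged 16.1 in WT and 126 in R502W at 3 weeks, and 132 and 2494 at 18 weeks, while Col3a1 was lower at 18 weeks in both genotypes.

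At 3 weeks, R502W hearts already expressed transcripts of the fetal and stressed cardiomyocyte at several times the WT level. Myh7, the slow beta-myosin heavy chain of the fetal ventricle, rose 6.55-fold (log2 2.71, SE 0.41, limma adjusted p = 0.00055, n = 4 per group), from 16.1 ± 4.19 to 126 ± 78.3 (SD, n = 4). Nppb, which encodes B-type natriuretic peptide, rose 5.39-fold, from 19.5 ± 7.57 to 104 ± 22.9 (SD, n = 4; limma adjusted p = 1.0e-04). Acta1, skeletal alpha-actin, rose 3.41-fold from 94.6 ± 21.8 to 324 ± 62.0 (SD, n = 4), and the stretch-responsive repressor Ankrd1 rose 2.81-fold from 269 ± 47.8 to 749 ± 62.3 (SD, n = 4). Mybpc2, the fast skeletal paralog of Mybpc3 (log2 1.99), and Casq1, skeletal calsequestrin (1.77), rose as well. The cytokine receptor Tnfrsf12a (1.73) and the matrix protein Cilp (1.57) were among the other large rises. Among the falls were those of Cenpf, a kinetochore protein (-1.09), the sorting receptor Sorcs2 (-0.89), the clock-output factors Dbp and Hlf (both -0.84), the lipogenic regulator Mid1ip1 (-0.78), Klhl33 (-0.77), monoamine oxidase Maob (-0.76) and Lgals4 (-0.74).

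By preset list, 12 of 19 measured fetal and hypertrophic cardiomyocyte genes rose at 3 weeks and none fell, 12 also when adjusted over the list alone, with a median log2 difference of 0.76 (camera adjusted p = 1.6e-16). It was the 1 list of this comparison whose call held with an estimated correlation (adjusted p = 0.0183). Xirp2, an intercalated-disc protein, rose by 0.99, and the atrial natriuretic peptide gene Nppa, at 496 ± 192 in WT and 1168 ± 403 in R502W (SD, n = 4), did not pass the test (1.26, adjusted p = 0.283). Among collagens and fibrosis genes, 13 of 34 rose, 0 fell and 21 did not pass, and 28 rose when adjusted over the list alone. The median was 0.45 (camera adjusted p = 1.4e-17; adjusted p = 0.191 with an estimated correlation). Thbs4 (1.68), Col8a1 (1.06), Postn (0.75) and Tgfb2 (0.68) rose. The main fibrillar collagens Col1a1 (0.50, adjusted p = 0.0930) and Col3a1 (0.39, adjusted p = 0.137) did not pass the test. Cell cycle and mitosis genes were higher as a list (median 0.44, camera adjusted p = 1.0e-08; adjusted p = 0.253 with an estimated correlation), with 6 of 36 risen and 1 fallen, or 15 and 1 when adjusted over the list alone. Mki67 (0.79) and Top2a (0.71) were among the risen, and the 1 fallen member was Cenpf. These 3 genes lost their calls without WT sample 2, R502W sample 2 or R502W sample 4, and Top2a also without WT sample 4, with an adjusted p of up to 0.0752 for Cenpf, 0.0840 for Mki67 and 0.107 for Top2a.

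Lists of nuclear genes of energy metabolism were lower at 3 weeks by camera with its preset correlation, with small median differences. Of 44 respiratory chain subunits 29 fell and 0 rose, and 43 fell when adjusted over the list alone (median -0.22, camera adjusted p = 1.4e-27; adjusted p = 0.191 with an estimated correlation). The cytochrome c oxidase subunits Cox7a1 (-0.46), Cox8b (-0.38) and Cox5b (-0.25) had the smallest p-values. Fatty acid oxidation followed, with 17 of 29 fallen, 0 risen and 24 fallen when adjusted over the list alone (median -0.24, camera adjusted p = 1.3e-18; adjusted p = 0.191 with an estimated correlation). They included the thiolase Acaa2 (-0.43), the dienoyl-CoA reductase Decr1 (-0.42) and the carnitine palmitoyltransferase Cpt2 (-0.35). In the tricarboxylic acid cycle 4 of 20 fell, or 17 when adjusted over the list alone (median -0.16, camera adjusted p = 3.8e-09; adjusted p = 0.253 with an estimated correlation). Transcripts of the mitochondrial genome had a median of -0.22 with 1 of 15 fallen (camera adjusted p = 0.000564; adjusted p = 0.442 with an estimated correlation). That list lost its call under quantile normalization (camera adjusted p = 0.238). Reads of mitochondrial genes can be shared with their nuclear copies, so these values are uncertain. Ventricular cardiomyocyte markers were lower as a list in the same comparison (median -0.13, camera adjusted p = 0.00451; adjusted p = 0.442 with an estimated correlation), with 1 of 12 fallen, or 2 over the list alone. The fallen member was Tnni3, cardiac troponin I (-0.33), and the calls of the list (camera adjusted p = 0.954) and of Tnni3 (limma adjusted p = 0.846) were lost under quantile normalization. Tnni3 also lost its call without WT sample 2. Potassium channel subunits Kcnv2 (-0.67) and Kcnd2 (-0.58) were among the cardiac ion channels, of which 3 of 24 had fallen and 6 when adjusted over the list alone (camera adjusted p = 0.000285; adjusted p = 0.191 with an estimated correlation). The calcium pump gene Atp2a2 (-0.27, adjusted p = 0.104), its inhibitor Pln (-0.29, adjusted p = 0.0570) and Myh6, the adult alpha-myosin heavy chain (-0.11, adjusted p = 0.70), did not pass the test.

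In all, 907 of 14109 genes differed between genotypes at 3 weeks by limma, 442 higher and 465 lower in R502W, of which 37 were at least 2-fold higher and 5 at least 2-fold lower. Of 46 gene lists, 19 were called by camera with its preset correlation and 13 by fry. The gene count fell to 484 without R502W sample 2, to 493 without WT sample 2 and to 592 without R502W sample 3.

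At 18 weeks, R502W hearts again expressed fetal and stress transcripts at several times the WT level. Myh7 rose by 4.32 on the log2 scale (SE 0.41, limma adjusted p = 1.3e-06), from 132 ± 77.3 to 2494 ± 1069 (SD, n = 4). Acta1 rose 11.7-fold from 151 ± 42.2 to 1770 ± 493 (SD, n = 4; limma adjusted p = 8.2e-09), Nppb 4.11-fold from 78.9 ± 33.8 to 303 ± 60.3 (SD, n = 4) and Ankrd1 3.39-fold from 818 ± 142 to 2771 ± 468 (SD, n = 4). Casq1 (log2 2.61) and Mybpc2 (2.60) again rose, with the immediate early factor Egr1 (1.94), Cilp (1.88) and Abra (1.79), an actin-binding activator of serum response factor. Among the falls were those of Sorcs2 (-1.24), the matrix protein Emilin2 (-0.94), the secreted phospholipase Pla2g5 (-0.95), and Mbd1 (-0.96), Zfp970 (-0.92) and Ppip5k2 (-0.91). Mbd1 averaged 39.8 in WT and 39.4 in R502W at 3 weeks, and 86.9 ± 28.1 and 42.0 ± 2.95 at 18 weeks (SD, n = 4). Zfp970 averaged 43.5 and 32.8 at 3 weeks, and 70.4 and 36.6 at 18 weeks. For both genes WT at 18 weeks was the highest group.

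The fetal and hypertrophic list had 14 of 19 members risen and 0 fallen at 18 weeks, or 15 and 1 when adjusted over the list alone (median 1.29, camera adjusted p = 4.1e-19), and was again the 1 list whose call held with an estimated correlation (adjusted p = 0.00845). Synpo2l (1.55), Xirp2 (1.27) and Enah (0.97) belonged to it. Of 28 sarcomere components 11 rose and 1 fell, or 13 and 2 when adjusted over the list alone (median 0.15, camera adjusted p = 0.000146; adjusted p = 0.415 with an estimated correlation), among them Flnc (0.63), Des (0.47) and Csrp3 (0.43). The small heat-shock proteins Hspb7 (0.69), Hspb6 (0.66) and Hspb1 (0.52) were among the 7 of 25 protein quality control genes that rose, against 1 that fell, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.376 with an estimated correlation). Immediate early genes rose in 8 of 22 members and fell in 0, or 13 and 0 when adjusted over the list alone (median 0.54, camera adjusted p = 4.4e-08; adjusted p = 0.290 with an estimated correlation), including Atf3 (1.23) and Myc (1.07). Among collagens and fibrosis genes 17 of 34 rose and 0 fell, or 21 and 0 when adjusted over the list alone (median 0.46, camera adjusted p = 1.5e-12; adjusted p = 0.356 with an estimated correlation). Tgfb2 (1.17), Col8a1 (0.99), Ccn2 (0.97), Postn (0.76) and the proteoglycan Lum (0.61) rose. Col3a1 rose by 0.51 (adjusted p = 0.0342, a call that 12 of 33 alternatives ended, with an adjusted p of up to 0.125), and Col1a1 (0.51, adjusted p = 0.0667) did not pass the test.

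Respiratory chain subunits fell in 9 of 44 members at 18 weeks, or 13 when adjusted over the list alone (median -0.13, camera adjusted p = 4.5e-12; adjusted p = 0.415 with an estimated correlation). Fatty acid oxidation genes fell in 11 of 29, or 18 over the list alone (median -0.20, camera adjusted p = 1.5e-10; adjusted p = 0.376 with an estimated correlation), with 0 risen in either list. Cox7a1 (-0.57), Cox8b (-0.42) and Acaa2 (-0.42) were among the fallen. The tricarboxylic acid cycle had 5 of 20 fallen, or 10 over the list alone (camera adjusted p = 1.7e-05; adjusted p = 0.437 with an estimated correlation), including citrate synthase Cs (-0.27). Cardiac ion channels fell in 8 of 24 members, or 9 over the list alone (median -0.18, camera adjusted p = 0.000111; adjusted p = 0.290 with an estimated correlation), including Kcnj12 (-0.54), Abcc9 (-0.54) and Kcnh2 (-0.56). Myh6 (-0.24, adjusted p = 0.221), Atp2a2 (-0.27, adjusted p = 0.0735), Pln (-0.27, adjusted p = 0.0573) and the protease inhibitor Timp1 (0.12, adjusted p = 0.827) did not pass the test.

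The limma test called 1509 genes at 18 weeks, 790 higher and 719 lower in R502W, with 75 at least 2-fold higher and 15 at least 2-fold lower. Camera called 16 of 46 lists and fry 15. The count was 951 when the 8 libraries compared were fitted alone and 934 without R502W sample 4.

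Atrial transcripts varied widely between libraries within a group, and Nppa moved with them. The atrial light chain Myl7 was 0.760 in R502W 3 weeks sample 1 against 85.8 to 305 in the other 3 libraries of that group. In WT at 18 weeks it ranged from 9.43 to 263. The mean log2 level of Myl7, Myl4, Sln and Mybphl was 0.62 in R502W 3 weeks sample 1, 5.26 to 7.10 in the other libraries of its group, 4.70 to 6.13 in WT at 3 weeks, 2.76 to 7.15 in WT at 18 weeks and 5.27 to 7.28 in R502W at 18 weeks. Nppa was 474 ± 613 in WT and 1468 ± 513 in R502W at 18 weeks (SD, n = 4), a rise of 2.54 (SE 0.63, limma adjusted p = 0.0133). With the atrial mean as a covariate, an alternative chosen after seeing the data, the rise was 1.67 (adjusted p = 0.0300). The difference at 3 weeks was then 1.52 (adjusted p = 0.0346), past the threshold. The call at 18 weeks was lost when only the 8 libraries compared were fitted, with a robust spread, and with edgeR or DESeq2 on the recovered reads. Without R502W 3 weeks sample 1 and WT 18 weeks sample 2, limma called 1004 genes at 3 weeks and 1256 at 18 weeks. Myl7 and Myl4 also belong to the fetal list, whose call held with the covariate at both ages. Ucp1, the uncoupling protein of brown fat, chosen after its values were seen, ranged from 0.0217 to 0.786 in WT and from 0.0230 to 6.03 in R502W at 3 weeks. At 18 weeks it ranged from 0.0234 to 0.0255 in WT, where it had 0 reads, and from 0.0255 to 2.88 in R502W. The adipocyte list did not pass the test at 3 weeks (camera adjusted p = 0.511) or at 18 weeks (camera adjusted p = 0.868). The Y-linked gene Ddx3y lay between 88.2 and 113 in all 16 libraries.

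**Figure D2:**
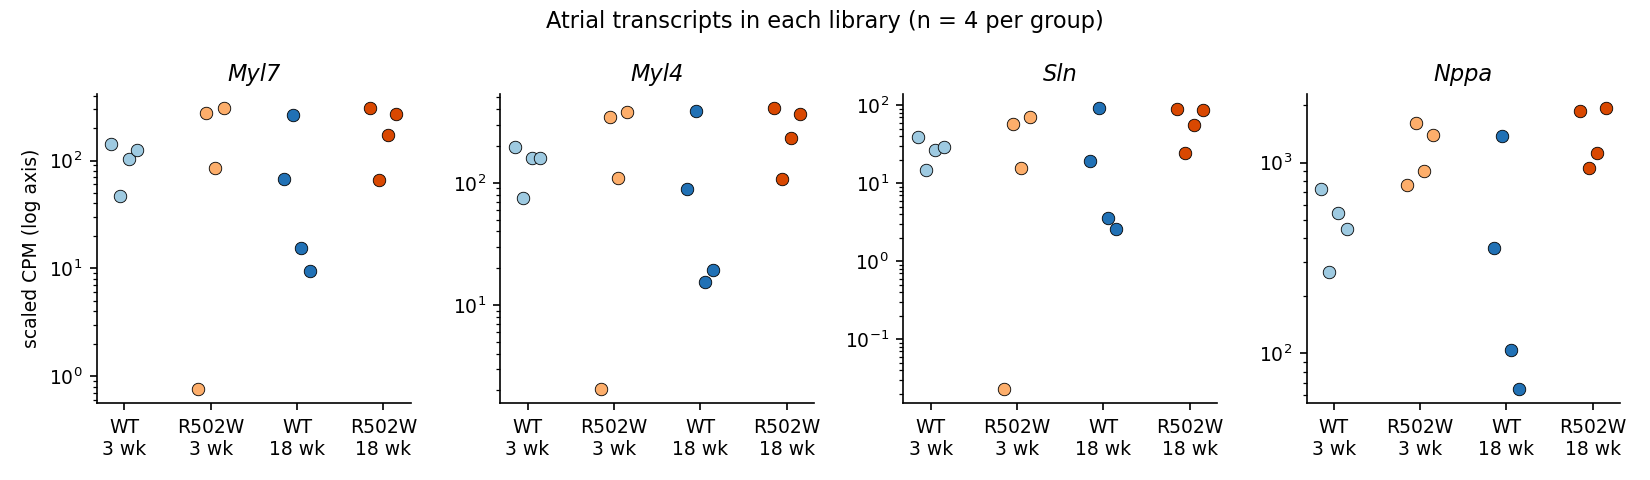
Scaled CPM (log axis) of the atrial transcripts Myl7, Myl4, Sln and Nppa in each library, 4 points per group. Myl7 was 0.760 in R502W 3 weeks sample 1 and 85.8 to 305 in the other libraries of that group.

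The genotype effects at both ages pointed the same way for most called genes. Of the genes tested, 260 were higher in R502W at both ages (24.7 expected from independent lists), among them Myh7, Acta1, Nppb, Casq1 and Mybpc2, and 204 were lower at both ages (23.7 expected), among them Sorcs2, Cox7a1 and Acaa2. None was called in opposite directions by limma (48.6 expected), and 93.7% of the genes called at 3 weeks had the same sign at 18 weeks. Across all 14109 genes the effects correlated with Pearson's r = 0.48 and Spearman's rho = 0.39, with a jackknife SE of 0.0837 for r over the libraries. The comparisons share no library, and genes are not independent replicates, so no p-value is given.

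**Figure D3:**
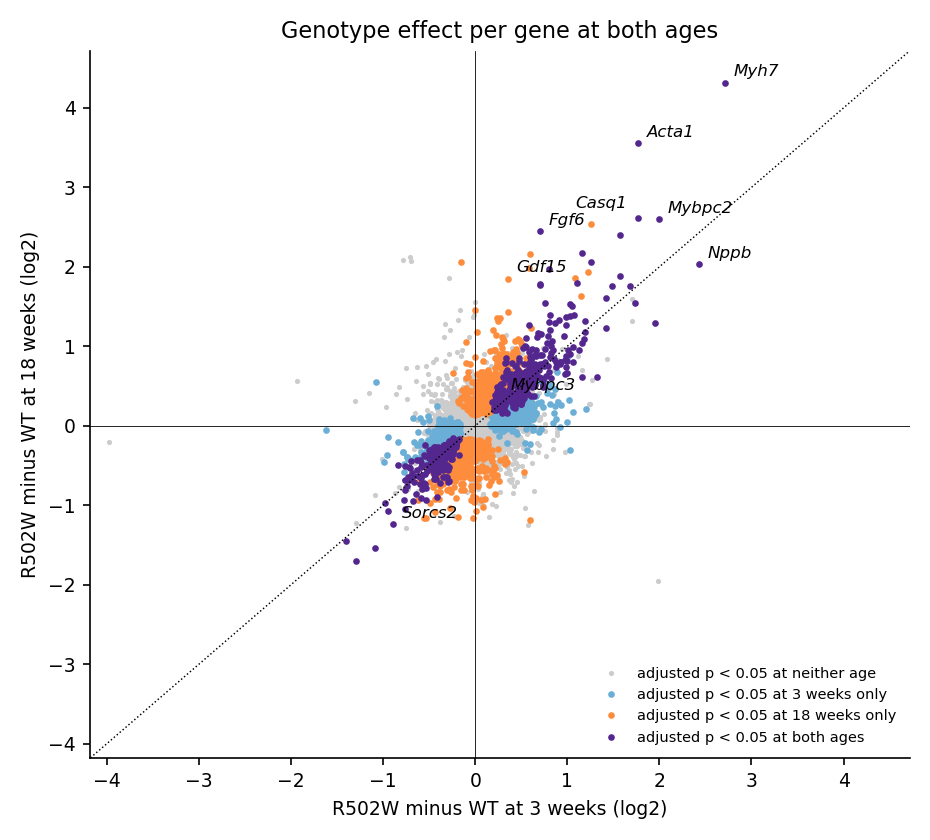
Log2 difference between R502W and WT at 18 weeks against that at 3 weeks for each of the 14109 genes, coloured by the age at which limma's adjusted p was below 0.05. Myh7 lies at 2.71 and 4.32 and Acta1 at 1.77 and 3.55, above the dotted line of equal effects, and Sorcs2 lies at -0.89 and -1.24.

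WT hearts at 18 weeks differed from those at 3 weeks in stress-protein, catabolic, matrix and growth transcripts. Bdh1, a ketone body dehydrogenase, rose 23.9-fold (log2 4.58, SE 0.16, limma adjusted p = 1.2e-12), from 2.58 ± 0.355 to 86.5 ± 20.2 (SD, n = 4), and the sodium channel beta subunit Scn4b rose 12.6-fold from 3.77 ± 0.967 to 58.9 ± 10.4 (SD, n = 4). Prostaglandin D synthase Ptgds (2.47), the Z-disc protein Myot (2.19) and the guanylate-binding protein Gbp6 (1.96) also rose. Myh7 (2.82) and Nppb (1.93) rose with age in WT as well. Elastin (Eln) fell 6.51-fold from 171 ± 37.7 to 25.2 ± 4.10 (SD, n = 4; limma adjusted p = 1.6e-06), Acta2, smooth muscle actin, fell by 2.62 on the log2 scale, the transferrin receptor Tfrc by 2.45 and Col3a1 by 2.31. Casq1 (-2.18), the growth factor Igf2 (-1.93), the imprinted gene Peg3 (-1.82) and the uncoupling protein Ucp3 (-1.81) also fell.

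Collagens and fibrosis genes fell with age in 21 of 34 members and rose in 1, or 22 and 1 over the list alone (median -0.80, camera adjusted p = 3.6e-12; adjusted p = 0.294 with an estimated correlation), including Fbn1 (-1.73), Loxl2 (-1.58) and Sparc (-1.43). Fibroblast markers fell in 12 of 16 members and rose in 1, or 13 and 1 over the list alone. Their median was -0.48 (camera adjusted p = 9.7e-07, or 0.0781 with an estimated correlation). Matrix genes and fibroblast markers thus moved together, though the lists share Col1a1, Col1a2, Lum and Mfap5. The imprinted growth network fell in 12 of 16 members and rose in 0, over the list alone likewise 12 and 0 (median -0.66, camera adjusted p = 1.0e-06; adjusted p = 0.0231 with an estimated correlation). In the list of heat shock and protein quality control 20 of 25 rose and 1 fell, or 20 and 2 over the list alone (median 0.64, camera adjusted p = 3.6e-12; adjusted p = 0.0365 with an estimated correlation), including the chaperone Hsph1 (1.57) and the muscle ubiquitin ligase Trim54 (1.54). Oxidative stress genes rose in 14 of 22 members and fell in 2, or 16 and 2 over the list alone (median 0.43, camera adjusted p = 2.0e-08; adjusted p = 0.0231 with an estimated correlation), with the glutathione transferase Gstm2 (0.84), Nqo1 (0.80) and the peroxidase Gpx4 (0.77). Ketone and branched-chain amino acid catabolism rose in 13 of 19 members and fell in 0, or 14 and 0 over the list alone (median 0.32, camera adjusted p = 3.5e-09; adjusted p = 0.122 with an estimated correlation). Fatty acid oxidation genes rose in 18 of 29 with 3 fallen, or 19 and 3 over the list alone (median 0.20, camera adjusted p = 0.000137; adjusted p = 0.678 with an estimated correlation). The fallen included Ucp3 and the pyruvate dehydrogenase kinase Pdk4 (-1.56). Respiratory chain subunits (camera adjusted p = 0.322), the tricarboxylic acid cycle (camera adjusted p = 0.586) and mitochondrially encoded transcripts (camera adjusted p = 0.756) did not pass the test with age in WT. Respiratory chain subunits passed it downward under quantile normalization (camera adjusted p = 3.6e-05) and without WT 18 weeks sample 4 (camera adjusted p = 0.0348). Limma called 4264 genes with age in WT, 2231 higher and 2033 lower at 18 weeks, with 156 at least 2-fold higher and 116 at least 2-fold lower.

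In R502W hearts the same comparison of ages called 5048 genes, 2606 higher and 2442 lower at 18 weeks, with 173 at least 2-fold higher and 128 at least 2-fold lower. Bdh1 rose by 4.59 (SE 0.16, limma adjusted p = 1.1e-12), Myh7 by 4.43, Scn4b by 3.52, Myot by 3.26, Abra by 2.51 and Acta1 by 2.43, with the class II gene H2-Aa (1.88) and Ankrd1 (1.87) also risen. Eln fell by 3.32 (SE 0.29, limma adjusted p = 8.5e-08), Acta2 by 2.45, Tfrc by 2.25 and Col3a1 by 2.19, and the matrix genes Frem2 (-1.90) and Fbn1 (-1.74), the channel regulator Pirt (-1.75) and Igf2 (-1.69) also fell. Cell cycle and mitosis genes fell in 25 of 36 members and rose in 0, or 27 and 0 over the list alone (median -0.60, camera adjusted p = 5.4e-07; adjusted p = 0.382 with an estimated correlation), including Mki67 (-1.05) and Ndc80 (-0.86). In WT the same list had 10 members fallen and 0 risen, or 9 and 0 over the list alone (median -0.37, camera adjusted p = 0.000378; adjusted p = 0.613 with an estimated correlation), a call lost without the genes of lowest level (camera adjusted p = 0.147). Sarcomere components rose in 15 of 28 members and fell in 2 in R502W, or 15 and 3 over the list alone (median 0.27, camera adjusted p = 0.000122; adjusted p = 0.402 with an estimated correlation), including Lmod2 (1.15) and Cryab (0.88), a call lost under quantile normalization (camera adjusted p = 0.826). The fetal and hypertrophic list rose in 11 of 19 and fell in 1, over the list alone likewise 11 and 1 (median 0.86, camera adjusted p = 6.6e-06; adjusted p = 0.167 with an estimated correlation). Collagens and fibrosis genes again fell in 21 of 34 and rose in 1, or 22 and 2 over the list alone (median -0.79, camera adjusted p = 6.3e-10; adjusted p = 0.382 with an estimated correlation). Fibroblast markers fell in 8 of 16 and rose in 1, over the list alone likewise 8 and 1 (median -0.31, camera adjusted p = 0.000311; adjusted p = 0.209 with an estimated correlation). Camera called 22 lists with age in WT and 19 in R502W, and fry 21 and 24. Of the genes called in both genotypes, 1649 rose (412 expected from independent lists), 1381 fell (352 expected) and 5 moved in opposite directions (762 expected).

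**Figure D4:**
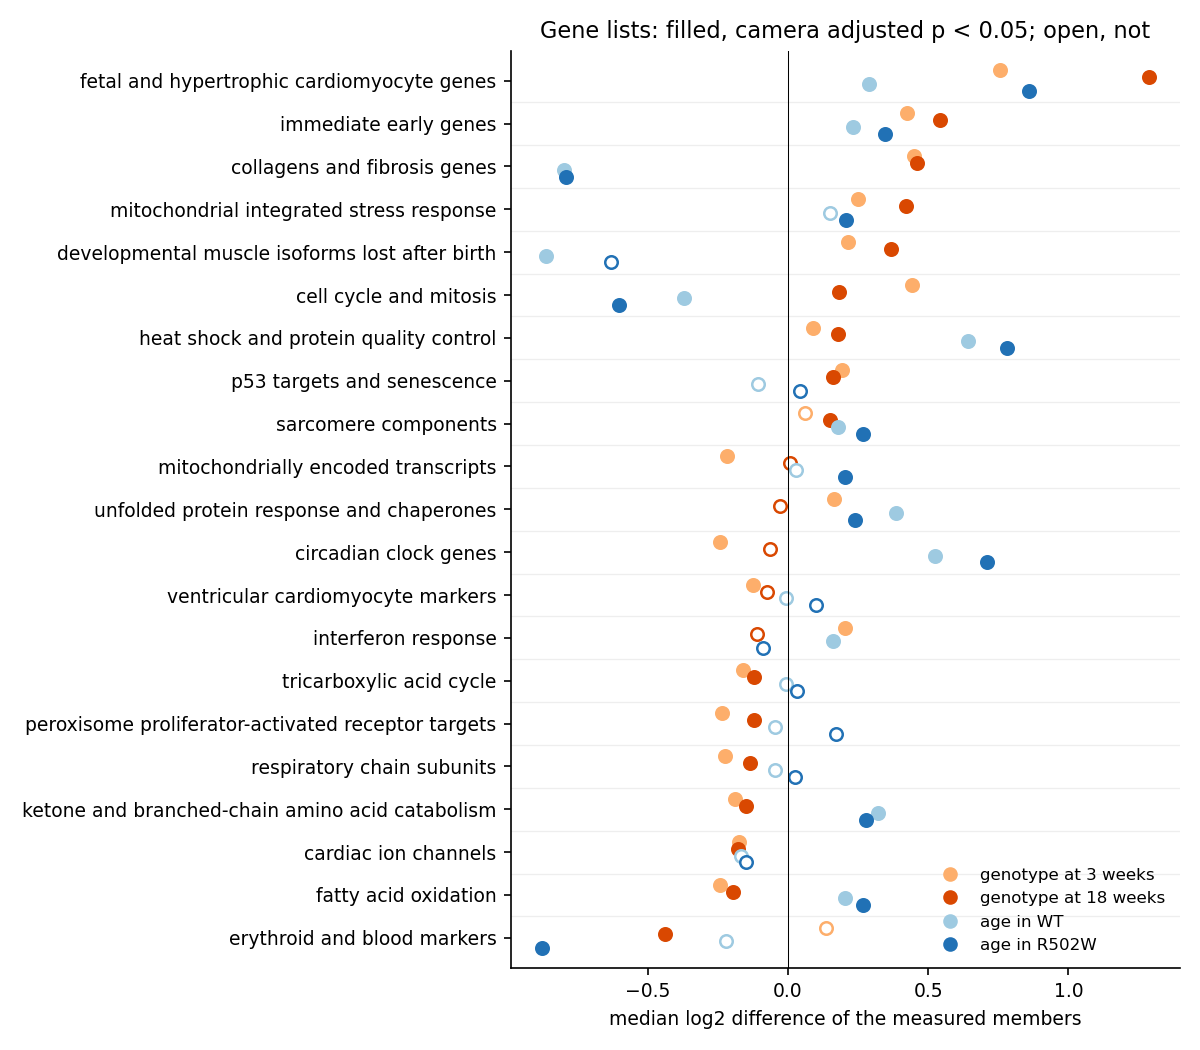
Median log2 difference of the measured members of 21 gene lists in the genotype and age comparisons, filled where camera with its preset correlation gave an adjusted p below 0.05. The fetal and hypertrophic list has medians of 0.76 and 1.29 between genotypes, and the collagens and fibrosis list has 0.45 and 0.46 between genotypes and -0.80 and -0.79 with age.

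Few genes were called for a genotype effect that differed between ages. In the simulated data this test recovered only 38.8% of genes changed 1.5-fold, so few calls do not show equal effects. Acta1 gained 1.78 on the log2 scale at 18 weeks over its genotype effect at 3 weeks (SE 0.30, limma adjusted p = 0.0283), Abra 1.09 (adjusted p = 0.0441), Myot 1.07 (adjusted p = 0.0394) and the stress cytokine Gdf15 2.82-fold (adjusted p = 0.0394). These calls were lost under 15 (Acta1), 21 (Abra) and 18 (Myot) of 32 alternatives and 17 of 30 for Gdf15, which is too low for the filters on level, edgeR among them for each gene, with an adjusted p of up to 0.374. For Myh7 the difference was 1.61 (adjusted p = 0.328), for Nppb -0.39 (adjusted p = 0.779) and for Nppa 1.28 (adjusted p = 0.631), which did not pass the test. Of 14109 genes, 1496 had an unadjusted limma p below 0.05, a larger share than the 0.05 that chance alone would give on average. Limma called 11 genes after adjustment, 9 with a larger and 2 with a smaller or more negative effect at 18 weeks. Under quantile normalization the split was 7 and 4, and under median-of-ratios rescaling 10 and 4. With edgeR on the recovered reads 0 genes were called and with DESeq2 106, and leaving out single libraries gave between 0 and 82, so the count is unstable. Camera called 13 lists, of which 0 held with an estimated correlation and fry called 0. The fetal and hypertrophic list had 2 members higher and 0 lower, or 5 and 1 over the list alone (median 0.28, camera adjusted p = 0.000245; adjusted p = 0.837 with an estimated correlation). The collagens and fibrosis list, with a median difference of 0.01, did not pass the test (camera adjusted p = 0.999).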

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

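Of the tests reported here, those on cardiomyocyte share, on length and GC content as the whole cause, on scaling, on immune cells, on variation shared by the interferon genes, on atrial tissue and on the depth of the library with few atrial markers were chosen only after the result was seen.

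R502W 18 weeks sample 4 lay apart from the other 3 libraries of its group in 3 measures. Its Postn level was 101 against 57.1 to 63.8, its share of mitochondrial reads 22.4% against 24.6% to 24.9%, and the share of its 10 largest genes 27.8% against 30.5% to 30.9%. Chance flags about 1 in 20 groups, and 3 of the 104 groups tested stood out, fewer than the 5.2 that chance would give. All 3 fell on this library, however, so the count does not show that it is ordinary. Its chi-square per degree of freedom was 30.2 to 35.4 against the other 3 libraries of its group. Among themselves those gave 7.36 to 10.4. WT 18 weeks sample 2 also lay apart by chi-square, with 24.1 to 40.7 against the other 3 libraries of its group. Among themselves those gave 9.41 to 12.3. The share of mitochondrial reads in WT 18 weeks sample 2 was 20.5% against 24.5% to 26.1%. The share of its 10 largest genes was 25.7% against 30.8% to 32.4%. These 2 shares were not among the 3 measures that stood out, so R502W 18 weeks sample 4 was not the only library apart at 18 weeks.

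The genotype effect differed between ages for 11 genes by limma. It was larger at 18 weeks for the contractile and stretch-responsive genes Acta1 (difference 1.78), Abra (1.09) and Myot (1.07), for the stress cytokine Gdf15 (1.496), for the growth factor Fgf6 (1.74) and the muscle transcription cofactor Vgll2 (1.45), and for Nlrc3 (1.57), Kcnc1 (1.13) and Lrrcc1 (1.07). It was lower for the predicted genes Gm49405 (-0.89) and Gm38394 (-0.61). The last 7 were named after their values were seen. In 6 of 100 draws of genotype labels within each age, the real one included, as many genes were called, and the highest other draw called 1165. The 5 draws with more genes, 1165, 220, 65, 42 and 18, kept or fully exchanged the genotype labels at 18 weeks, so they carry the genotype effect of that age, which is a structure of the samples. Draws that mixed the labels of that age called at most 3, but there the genotype effect adds to the spread. These draws therefore neither exclude chance for the count of 11 nor speak for it. For the genotype effect itself, 1 of 35 splits of the 8 libraries, the real one, gave as many genes at 3 weeks (907, highest other split 2) and 1 of 35 at 18 weeks (1509, highest other 18). With age it was 1 of 35 in WT (4264, highest other 2) and 1 of 35 in R502W (5048, highest other 3). In each case the real groups called by far the most genes. Yet 1 of 35 is the smallest share these splits can give, and splits that mix the groups add their difference to the spread. The splits therefore do not by themselves exclude chance for these 4 counts.

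Camera called 13 lists for the difference of the genotype effect between ages, of which 0 held with an estimated correlation and 0 were called by fry. Higher medians at 18 weeks were those of the fetal and hypertrophic genes (0.28), sarcomere components (0.11), respiratory chain subunits (0.076), mitochondrially encoded transcripts (0.24), ribosomal proteins (0.082), atrial markers (0.86) and clock genes (0.19). Lower ones were those of interferon response genes (-0.35), erythroid markers (-0.54), cell cycle genes (-0.21), unfolded protein response genes (-0.10), acute inflammation genes (-0.25) and glucocorticoid targets (-0.25). Camera's calls for sarcomere components (adjusted p = 0.887), respiratory chain subunits (adjusted p = 0.778) and mitochondrially encoded transcripts (adjusted p = 0.643) were lost under quantile normalization. The interferon, fetal and erythroid lists kept their call under the alternatives run other than the estimated correlation and fry. Apart from these and the sarcomere components, each list lost its call with at least 1 library left out, WT 18 weeks sample 3 for 6 of them.

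By camera with its preset correlation, but not with an estimated one, lists of nuclear genes of energy metabolism were lower in R502W hearts at 3 weeks. Of the respiratory chain subunits 29 of 44 were called, and smaller shares of the fatty acid oxidation and tricarboxylic acid cycle genes. A lower share of cardiomyocytes cannot be told apart from this fall. Against a mean of -0.23 (95% interval -0.34 to -0.12) for the respiratory chain, ventricular markers differed by -0.14 (-0.25 to -0.036). The ventricular list lost its call under quantile normalization (camera adjusted p = 0.954), where the respiratory chain kept a median of -0.17. Sarcomere components differed by 0.12 (0.0046 to 0.23), so the mean of -0.018 over 33 other cardiomyocyte genes decides nothing. Scaling is argued against as the whole cause, with a median of -0.17 under quantile normalization and -0.23 under median-of-ratios rescaling against -0.22. The smaller fall under quantile normalization leaves scaling open as a part. Genes matched on length, GC content and level had a median of -0.074 (sets from -0.16 to 0.01), which leaves length and GC content open as a part of the fall, while 0 of 44 matched sets fell as far as the list, which argues against them as the whole cause. An effect of the genotype on oxidative genes stays open, as a biological explanation that was not tested.

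Interferon response genes, with Usp18 (0.63) and Rsad2 (0.49) risen at 3 weeks, had a mean per library that was 0.20 higher in R502W at 3 weeks (exact two-sided permutation p = 0.0571) and -0.13 different at 18 weeks (exact p = 0.514). The difference between ages of -0.32 had an exact two-sided permutation p of 0.0869 over 4900 labelings, so variation shared by these genes between libraries is consistent with it and cannot be excluded. Dependence on 1 library is argued against, since the median difference stayed between -0.40 and -0.23 with each left out, the smallest without WT 18 weeks sample 3. The share of immune cells cannot be told apart from it, because macrophage and lymphocyte markers differed by -0.084 with a 95% interval of -0.36 to 0.19. Genotype and age stay open as biological explanations, which were not tested.

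Atrial markers were nearly absent from R502W 3 weeks sample 1, which had 16 reads of Myl7, where the mean level of the other 3 libraries would give 4842 at its depth, so depth is excluded. Of 11 other measured atrial markers 7 were lowest in this library, including Dkk3 (10.2 against 42.1 to 68.7) and Stard10 (7.49 against 14.3 to 43.5), while Kcna5 was highest (28.7 against at most 26.7). Bmp10 was at the value of 0 reads in this library (0.0230) and in another of its group (0.0154), a tie that was not counted. Less atrial tissue in the sample may explain the pattern. By the rule set for the test 7 of 11 is too few to decide, also with this tie added. For Nppa at 18 weeks, the log2 difference was 2.54 and, with the atrial covariate, 1.67 (SE 0.46, limma adjusted p = 0.0300). That fit used 1 slope for all 16 libraries. In R502W 3 weeks sample 1 the atrial mean was 0.62, yet Nppa was 759, against 902 to 1608 in the rest of its group. The shared slope may therefore be too shallow for 18 weeks. The fit cannot decide whether the amount of atrial tissue is the whole cause of the Nppa difference or a part. No biological explanation of the atrial pattern was tested, since the design gives none within a group.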

How the results depend on the processing

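The atrial covariate, the fit without 2 libraries, the GC correction and the thinning were tests chosen only after the result was seen. The count of genes with a genotype effect that differs between ages, 11, depended most on the processing. It was 0 with a pseudocount of 0.25, 25 with a pseudocount of 5, 4 and 8 with the milder and the stricter filter on low levels, 4 without the mean-variance trend, 21 with library weights, 0 with edgeR and 106 with DESeq2, of which 7 are among the 11. It was 28 with the atrial covariate, 17 with the GC correction and 7 after thinning. Leaving out libraries gave 0 (without WT 3 weeks sample 3, R502W 3 weeks sample 3 or WT 18 weeks sample 1) to 82 (without WT 18 weeks sample 4). The unadjusted count was 1496. The cause was not tested.

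At 18 weeks the genotype count of 1509 was 951 with only the groups compared, and 934 to 1497 with single libraries left out, the lowest without R502W 18 weeks sample 4. At 3 weeks the count of 907 was 1080 with only the groups compared, 1328 with library weights, 1193 with DESeq2, 1114 with the atrial covariate and 637 without the mean-variance trend, and ranged from 484 (without R502W 3 weeks sample 2) to 1051 with single libraries left out. The cause was not tested. The correlation of the genotype effects between ages, 0.48, was 0.62 without the genes below the median level, and 0.43 to 0.49 with single libraries left out. Mybpc3 kept the direction of its genotype and age effects in every setting run. Its genotype effect ranged from 0.27 to 0.34 at 3 weeks with single libraries left out, and was 0.47 under quantile normalization, and its age effect in WT from 0.19 to 0.28. Under quantile normalization the age effect of Mybpc3 was 0.15 in WT and 0.069 in R502W, neither past the test, and the cause was not tested.

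With an estimated correlation 1 list was called at 3 weeks, 1 at 18 weeks, 3 with age in WT, 0 with age in R502W and 0 for the interaction, for which fry called 0 as well. Without the genes below the median level, 14 lists instead of 22 were called with age in WT, where fewer genes were tested. Interaction lists ranged from 7 (without WT 18 weeks sample 3) to 18. Under quantile normalization 4 list results changed direction and passed the test downward: respiratory chain subunits (camera adjusted p = 0.000411) and the tricarboxylic acid cycle (camera adjusted p = 0.00250) with age in R502W, and the tricarboxylic acid cycle (camera adjusted p = 0.0163) and ventricular markers (camera adjusted p = 0.0402) for the interaction. The cause was not tested.

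With the sample number as a replicate block, 0 genes were called for the interaction, 771 at 3 weeks, 1336 at 18 weeks, 4117 with age in WT and 4932 with age in R502W. Samples with the same number deviated together with correlations of -0.16 to 0.13, and 1 pair at 3 weeks was over 0.1. Samples with different numbers reached -0.20 to 0.19. The correlations thus show no pairing by number but cannot exclude it, and the labels do not say what the numbers mean. Own number was the best match for 2 of 4 pairs at 3 weeks, 0 at 18 weeks, 1 with age in WT and 1 with age in R502W. The planned sex covariate was not run, because the female-expressed gene it needs is not among the genes measured. The 4 measured Y-linked genes were expressed in all 16 libraries, which gives no sign of a library from females alone. Their lowest values were 88.2 (Ddx3y), 48.3 (Eif2s3y), 18.4 (Kdm5d) and 25.3 (Uty). Of the named genes called, 43 of 73 at 3 weeks, 58 of 70 at 18 weeks, 90 of 95 with age in WT, 81 of 85 with age in R502W and 0 of 4 for the interaction kept their call in every setting run. Of the lists, 12 of 19, 13 of 16, 12 of 22, 13 of 19 and 3 of 13 did, apart from the estimated correlation and fry.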

Other observations

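The tests on clock genes were chosen only after the result was seen.

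Antigen presentation transcripts were higher as a list at 18 weeks than at 3 weeks in both genotypes. Cd74, the invariant chain, averaged 22.6 and 78.8 in WT (log2 1.70, limma adjusted p = 4.0e-05) and 22.5 and 81.2 in R502W (log2 1.76, limma adjusted p = 2.3e-05). Of 17 listed genes 13 rose and 0 fell in WT, or 15 and 0 when adjusted over the list alone (camera adjusted p = 9.7e-07; adjusted p = 0.446 with an estimated correlation), and 13 and 0 in R502W, again 15 and 0 over the list alone (camera adjusted p = 2.5e-05; adjusted p = 0.479 with an estimated correlation). Macrophage markers did not pass the test with age in WT (camera adjusted p = 0.756) or in R502W (camera adjusted p = 0.117). Class II genes are a multigene family and their single values are uncertain.

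Red cell transcripts were lower as a list in R502W hearts at 18 weeks by camera with its preset correlation. The median was -0.44 over 10 genes (camera adjusted p = 0.00092, or 0.376 with an estimated correlation), of which 1 fell, or 3 over the list alone. With age in R502W 7 of the 10 fell and 0 rose, or 8 and 0 over the list alone (camera adjusted p = 0.00218; adjusted p = 0.398 with an estimated correlation), including Hbb-bt (-1.59), whose reads can be shared with other globin genes.

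Mitochondrial stress transcripts were higher as a list in R502W at both ages by camera with its preset correlation. At 18 weeks 5 of 17 rose and 1 fell, or 11 and 1 over the list alone (camera adjusted p = 2.9e-05; adjusted p = 0.304 with an estimated correlation), with Gdf15 (1.85), the folate enzyme Mthfd2 (1.33) and the transcription factor Atf5 (0.58) risen. At 3 weeks 2 rose and 0 fell, or 4 and 0 over the list alone (camera adjusted p = 0.00106; adjusted p = 0.296 with an estimated correlation), with Mthfd2 (0.91) and the proline synthesis enzyme Aldh18a1 (0.57). Immediate early genes were also higher as a list at 3 weeks, where 4 of 22 rose and 0 fell, or 10 and 0 over the list alone. The camera adjusted p was 2.6e-07, or 0.191 with an estimated correlation. The risen included Egr3 (0.93), Btg2 (0.62) and Jun (0.60).

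With age in WT, unfolded protein response genes rose in 17 of 24 members and fell in 1, or 18 and 1 over the list alone (camera adjusted p = 3.2e-08; adjusted p = 0.122 with an estimated correlation), including Ddit3 (0.91) and the secreted factor Manf (0.86). Hypoxia response genes rose in 10 of 20 and fell in 3, or 11 and 3 over the list alone (camera adjusted p = 0.00375; adjusted p = 0.122 with an estimated correlation), including the prolyl hydroxylase P4ha1 (0.88) and Pdk1 (0.70).

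A first hypothesis, written before its result was seen, was that R502W hearts at 3 weeks are less mature than WT hearts, so that the genotype effect would run against the change with age in WT. With the WT 3 weeks libraries split so that the comparisons share no library, the median Pearson r across genes over 6 splits was 0.0292 (0.00474 to 0.0925), and Spearman's rho lay between -0.0285 and 0.0570. Among the 907 genes called at 3 weeks r lay between 0.208 and 0.290. Those genes were picked with all WT 3 weeks libraries, also those of the age comparison. That choice can push r upward, so it decides nothing. The values across all genes argue against a delay across all genes, for which r was predicted to be -0.1 or lower. A delay of some genes stays open. The cell cycle list and the collagens and fibrosis list were higher in R502W at 3 weeks and fell with age in WT. Genes are not independent replicates.

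A second hypothesis was that the hearts of the groups were taken at different phases of the circadian clock. At 3 weeks the mean of Arntl, Npas2 and Clock was 0.36 higher in R502W (exact two-sided permutation p = 0.0857), and that of Dbp, Tef, Hlf, Per3 and Nr1d1 was -0.57 different (exact p = 0.0286, 0.0457 after adjustment over 8 tests), where 0.0286 is the smallest p that 4 against 4 can give. At 18 weeks the differences were 0.35 (exact p = 0.0571) and -0.25 (exact p = 0.0571). With age the means moved by -1.04 and 0.49 in WT and by -1.05 and 0.81 in R502W (each exact p = 0.0286). Opposite movement of these arms is consistent with a phase difference, but the first arm did not pass at 3 weeks, and times of collection were not used here, so a phase difference and an effect of genotype or age on the clock cannot be told apart.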
